A study of Homo sapiens with 4 samples.

How the data were processed

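RNA of 3 lymphoma cell lines was compared on 4 two-colour arrays. Per the labels, total RNA of BCBL-1, a primary effusion lymphoma line, carried Cy5 on all 4 arrays. BJAB, labelled as a BL line, carried Cy3 on 2 arrays, and L-428, a classical Hodgkin's disease line, carried Cy3 on the other 2. No array had the dyes exchanged, so a dye bias of a probe is part of every ratio against BCBL-1.

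The authors deposited 1 log ratio per feature and array, taken here as log2. Per the labels, arrays were read with a GenePix 4000B scanner, and for 1 array the labels also name GenePix Pro 4 and GenTraffic. Background correction, normalization, spot filter and averaging of spots are not given in the sources used here. The base of the logarithm is not stated either. The range of the values is too wide for log10 ratios, but a natural logarithm is not excluded, and every fold below rests on base 2.

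The direction of the deposited ratio is not stated. It is likely BCBL-1 over the other line, because BCBL-1 carried Cy5 and the design text sets this line against BJAB. The label of 1 array calls its Cy3 sample, L-428, the experimental one, which would point the other way. If so, every direction given here turns.

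The table held 1613 features named by sequence accessions. Accessions were matched, without versions, to gene symbols of the RefSeq annotation of assembly GCF_000001405.40 (GRCh38.p14), used for names alone. A single symbol was found for 1360 features, none had several, and 253 had none, among them 43 of the 1403 RefSeq mRNA accessions. No gene had more than 1 feature. Values were missing for 14 and 19 features on the BJAB arrays A and B, and for 0 and 1 on the L-428 arrays A and B. The number of arrays limits the precision, and channel intensities were not used here.

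Each array was centred on its own median, and the 1586 features with a value on all 4 arrays were fitted with limma 3.58.1 in R 4.3.3, with a mean per group and empirical Bayes variances. The mean ratio of each group was tested against 0, and the difference of both means compared BJAB with L-428 through their common BCBL-1 channel. Tests were two-sided, with Benjamini-Hochberg adjustment over all features and a threshold of 0.05. The fit had 2 residual degrees of freedom and a prior of 1.98. Errors are limma's standard errors (SE). They rest on a variance per feature that both pairs of arrays share, so a wide pair also widens the SE of the other pair. The titles give both arrays of a group the same slide number with the letters A and B, so they may be parts of 1 slide. The p-values then measure only the spread between arrays, which may be technical, and slide and group cannot be told apart. A fold rule without a test counted features at least 2-fold from 0 on both arrays with 1 sign.

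The main tests, the gene lists, the rule for named genes and all alternatives were fixed before the data were examined. Some checks and gene families in the later sections were chosen after results were seen, and are named as such there. For BCBL-1 against each line, the rule took the 10 highest and the 10 lowest named features past the test and at least 2-fold on both arrays. For BJAB against L-428 it took the 5 highest and 5 lowest differences past the test, and for both lines the 5 highest and 5 lowest by the smaller of both means among features past both tests with 1 sign. Up to 4 members of each list with the largest mean were added, and genes of families with near-identical members were to be called uncertain. A gene that the rule takes is not reported here by name or value, and it stays in the counts.

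Of 20 gene lists, 18 had at least 5 measured genes and were tested with limma's camera at a preset correlation of 0.01. Its p-values were adjusted over 54 tests, and camera with an estimated correlation and fry were set beside it. With an estimated correlation camera's test has only the 2 residual degrees of freedom, so hardly any list could pass it. The lists covered B cell receptor and surface genes, B cell and germinal centre transcription factors, plasma cells, MHC class II, MHC class I, NF-kappaB, Hodgkin Reed-Sternberg cells, interferon response, cytokines, their receptors, angiogenesis and hypoxia, cell cycle, apoptosis, secretory pathway, ribosomal proteins, adhesion and cytoskeleton, T and NK cells, myeloid cells, reference genes, and DNA repair. Alternatives were values as deposited, quantile normalization, robust variances, a separate fit per group, fewer required values, stricter thresholds, the array letter as a replicate block, each array left out, and features with disagreeing arrays left out.

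The fit was tested on simulated data with the 1586 features. Against BJAB it recovered 90.3% of 300 changed features, with 3.9% false calls. By size, over 50 features each, it recovered 56% at 1.5-fold, 92% at 2-fold, 98% at 4-fold and 100% at 8-fold. The 100 features changed against BJAB alone are not in these rates by size. Against L-428 it recovered 82.5% of 200, with 5.2% false calls, and by size 42%, 90%, 100% and 98%. For the difference it recovered 89% of 100, with 4.3% false calls. These simulated arrays were independent, which the deposited arrays may not be. Fewer features were changed than the 919 and 670 called in the data, and the spread of the simulated variances was set by choice. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.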

Results

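Expression in BCBL-1, a lymphoma line grown from an effusion and known to carry Kaposi's sarcoma-associated herpesvirus, was set against BJAB, a B cell lymphoma line, and L-428, a line from Hodgkin's disease. Each comparison had 2 arrays, with BCBL-1 in the Cy5 channel. Values are read as log2 ratios of BCBL-1 over the other line, a likely direction that the labels do not state, and the base of the logarithm is not stated either. Array medians as deposited were −0.585 and −0.578 against BJAB and −0.349 and −0.337 against L-428, and all values below are relative to the median of their array. Within a pair the arrays correlated across features at r = 0.862 for BJAB and 0.836 for L-428, against 0.577 to 0.595 between arrays of different pairs. Features are not independent replicates.

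The first comparison asked which genes differ between BCBL-1 and BJAB. Genes of MHC class II and most measured genes of the B cell receptor fell, and 12 of 19 adhesion genes rose. CD74, the invariant chain of MHC class II, fell to a log2 ratio of −5.99 ± 0.11 (SE, n = 2 arrays, adjusted p = 8e-04), 63.6-fold lower. CD79A and CD79B, the signalling chains of the B cell receptor, fell to −5.49 ± 0.15 and −3.58 ± 0.16. LGALS1, which encodes galectin-1, rose to 4.33 ± 0.09 (adjusted p = 8e-04), 20.1-fold higher, and the calcium-binding protein gene S100A6 to 4.02 ± 0.10.

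Among other named genes, THBS1 (thrombospondin-1, a matrix glycoprotein) rose to 3.53 ± 0.10, SELPLG (the P-selectin ligand) to 3.26 ± 0.11 and IRF4 (a transcription factor of plasma cells) to 3.06 ± 0.23. EDNRB, an endothelin receptor, reached 2.59, the cytokine gene IL16 2.29, the interferon-induced OAS2 2.27 and LTA4H, of leukotriene synthesis, 2.15. GSTP1, a glutathione S-transferase, fell to −6.22 ± 0.42, the galactosyltransferase gene B4GALT1 to −5.60 ± 0.46, and LRRC32, which encodes a TGF-beta binding surface protein, to −5.05 ± 0.43. HLA-DQA1 fell to −4.11 ± 0.18 and the receptor gene CD40 to −3.77 ± 0.29. The arrays of the convertase gene PCSK6 stood far apart, at −2.47 and −5.73. Its mean of −4.10 had an adjusted p of 0.019, and with either L-428 array left out, which lowers the degrees of freedom and leaves its mean as it was, an adjusted p of 0.051. TCL1A, a B cell oncogene, fell to −3.45 ± 0.63, and without BJAB array A its value was −2.52 with an adjusted p of 0.0753.

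All 5 measured MHC class II genes fell against BJAB, with a median of −2.37 (camera, adjusted p = 0.00183, or adjusted p = 0.675 with an estimated correlation). HLA-DRB1 stood at −2.37, HLA-DQB1 at −1.87 and HLA-DPA1 at −1.62. Members of the HLA-DR and HLA-DQ families are near-identical, so which of them each probe reports is uncertain. Of 7 B cell receptor and surface genes 6 fell and 0 rose, with a median of −1.09 that was −1.67 as deposited (adjusted p = 0.00583, or adjusted p = 0.675 with an estimated correlation). They included SYK, a kinase of the receptor, at −1.09, and CD37 at −0.92, while CD24 at −0.30 did not pass. Of 19 adhesion, cytoskeleton and mesenchymal genes 12 rose and 3 fell, with a median of 0.68 that was only 0.10 as deposited (adjusted p = 0.0159, or adjusted p = 0.675 with an estimated correlation). SPARC rose to 2.03 and TIMP1 to 1.33, and the adhesion gene ICAM3 fell to −2.09, while 3 of the 12 higher calls ended as deposited and after quantile normalization. Counts adjusted over the list alone were the same for these 3 lists.

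Other lists did not pass the set test against BJAB. Of 5 plasma cell genes IRF4, SDC1 (1.19) and XBP1 (0.91) rose, JCHAIN, the joining chain of immunoglobulins, fell to −3.12 and CD27 at −0.48 did not pass. Of 7 NF-kappaB genes CD40, BCL2L1 (−2.0), RELB (−1.70) and NFKB2 (−0.98) fell and IL6 (1.18), TNF (0.65) and CD83 (0.57) rose, TNF and CD83 not passing as deposited (0.06 and −0.01). Of 20 ribosomal protein genes 11 rose and 2 fell, with a median of 0.33 that was −0.25 in the values as deposited (adjusted p = 0.0721). Of 14 cell cycle genes 7 fell, among them CCND3 (−1.18), TOP2A (−1.11), MCM6 (−1.02) and MCM5 (−1.0, adjusted p = 0.0568 without BJAB array B), and 2 rose, CDK4 and CDKN1A, neither passing as deposited (−0.003 and 0.13) or after quantile normalization. The median of the cell cycle list was −0.39, and −0.98 as deposited. Interferon response genes had 6 of 10 higher and 1 lower, with a median below 0 as deposited (−0.15), Hodgkin Reed-Sternberg genes 4 of 5 higher, cytokines 5 of 8 higher and 1 lower, and cytokine receptors 1 of 10 higher and 2 lower. Of 7 angiogenesis and hypoxia genes 2 rose and 3 fell, among the latter the endothelial adhesion gene PECAM1 (−3.38) and VEGFA (−1.45). As deposited the calls of 9 of the 11 higher ribosomal protein genes ended (7 after quantile normalization), RPL27A passing below 0 at −0.27 (adjusted p = 0.0494), as did those of 2 higher interferon genes, 2 cytokines, 1 receptor and 1 angiogenesis gene. After quantile normalization the numbers were 2, 2, 0 and 1.

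In all, 919 of 1586 features passed limma's test against BJAB, 504 higher and 415 lower, and 214 met the fold rule, 58 higher and 156 lower (23 and 392 as deposited). The split rests on the centring, since the values as deposited gave 98 higher and 904 lower and quantile normalization 131 and 810. Of 103 list members called against BJAB, 36 did not hold as deposited and 31 after quantile normalization. Without BJAB array A 540 features passed and without array B 495.

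The second comparison set BCBL-1 against L-428. CD48, a surface protein of leukocytes, rose to 4.16 ± 0.09 (SE, n = 2 arrays, adjusted p = 0.00076), 17.9-fold higher, and ARHGDIB to 4.10 ± 0.09, 17.2-fold higher. CD74 fell to −4.88 ± 0.11 (adjusted p = 0.00076), 29.4-fold lower, and HLA-DQA1 to −3.30 ± 0.18.

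THBS1 rose to 3.08, SELPLG to 2.87, the retinoic acid receptor gene RARA to 2.79, EDNRB to 2.41 and S100A6 to 2.34. B2M, the light chain of MHC class I, rose to 2.20, OAS2 to 2.19 and IFI30, a lysosomal reductase, to 2.10. The aromatase gene CYP19A1 fell to −3.65 ± 0.44, with arrays at −2.80 and −4.51, and CD200 to −2.96 ± 0.33, with arrays at −2.33 and −3.60. OMG, a myelin glycoprotein gene, fell to −2.88, YAP1, a coactivator of the Hippo pathway, to −2.82, HLA-DQB1 to −2.81 and TMSB4X, which encodes an actin-binding thymosin, to −2.63. GSTP1 at −3.57 ± 0.42 and the potassium channel gene KCNJ8 at −2.84 ± 0.33 passed limma's test with an adjusted p of 0.0094. The L-428 arrays of GSTP1 lay close, at −3.61 and −3.53, and its SE rests mostly on its BJAB arrays, at −5.40 and −7.04. Without L-428 array A GSTP1 and KCNJ8 stood at −3.53 and −2.43, and without array B at −3.61 and −3.25. Neither call held in these fits, which have fewer degrees of freedom.

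Of 20 ribosomal protein genes 18 rose and 0 fell against L-428, with a median of 0.78 that stayed above 0 at 0.44 as deposited (camera, adjusted p = 5.2e-06, or adjusted p = 0.675 with an estimated correlation). RPL32 (1.81), RPL21 (1.56) and RPL6 (1.47) stood highest of the 18, of which 5 did not pass as deposited and 6 after quantile normalization, the last 2 named with adjusted p of 0.0518 and 0.0502 without L-428 array B, and probes for such genes may also read their many processed copies. All 5 MHC class II genes in the fit fell, with a median of −2.81 (camera, adjusted p = 0.000379, or adjusted p = 0.675 with an estimated correlation). RFX5, of the same list but left out for missing BJAB values, read −0.70 and −0.49 against L-428. Counts adjusted over the list alone were the same for both lists.

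The remaining lists did not pass against L-428. Of 7 B cell receptor genes SYK rose to 0.92, CD40 (−1.36) and CD24 (−0.74) fell, and CD79A at −0.29 and CD79B at −0.07 did not pass. Without L-428 array A or B none of those 3 calls held in a fit with fewer degrees of freedom. There SYK stood at 0.91 and 0.92 (adjusted p = 0.0791 and 0.0776), CD40 at −1.37 and −1.36 (0.159 and 0.168) and CD24 at −0.79 and −0.69 (0.154 and 0.191). The adhesion list had 10 of 19 higher and 3 lower, with a median of 0.31 that was −0.04 as deposited (adjusted p = 0.122). Plasma cell genes had 3 of 5 higher, with a median of 0.47 that was 0.13 as deposited. Those 3, XBP1, JCHAIN and SDC1, no longer passed as deposited (0.15, 0.13 and 0.10, adjusted p of 0.27, 0.314 and 0.352), after quantile normalization (0.453 to 0.711) or without either L-428 array (0.104 to 0.171). NF-kappaB genes had 2 of 7 higher, of which IL6 did not pass as deposited (0.16, adjusted p = 0.204), and 4 lower, interferon genes 5 of 10 higher and 2 lower, and Hodgkin Reed-Sternberg genes 3 of 5 higher and 1 lower. Cell cycle genes had 2 of 14 higher and 2 lower, cytokines 3 of 8 higher and 1 lower with a median below 0 as deposited (−0.06), their receptors 3 of 10 higher and 2 lower, and angiogenesis genes 1 of 7 higher and 2 lower. Both higher cell cycle genes, CDKN1A and MCM2, did not pass as deposited (0.16 and 0.002, adjusted p = 0.163 and 0.989) or after quantile normalization. Of the other higher calls as deposited 2 ended in the adhesion list, 1 each in the Hodgkin and cytokine lists, 2 among the receptors and 0 in the interferon and angiogenesis lists. After quantile normalization 2 ended in the adhesion, NF-kappaB, cytokine and interferon lists, 1 in the Hodgkin list, 3 among the receptors and 0 in the angiogenesis list.

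In all, 670 features passed limma's test against L-428, 378 higher and 292 lower, and 161 of 1612 met the fold rule, 50 higher and 111 lower (31 and 209 as deposited). As deposited the split was 158 higher and 620 lower, and after quantile normalization 123 and 762. Without L-428 array A 61 features passed and without array B 59, the remaining array being assumed to vary like the BJAB pair. Of 91 list members called against L-428, 24 did not hold as deposited, 31 after quantile normalization, and 75 and 78 without L-428 array A and B.

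Further lists gave smaller groups in both comparisons. MHC class I genes had B2M higher (0.81 and 2.20) and PSME1, a proteasome activator, lower (−0.88 and −1.30) against BJAB and L-428, and PDIA3 lower against BJAB alone by the test (−1.02 and 0.22). As deposited B2M no longer passed against BJAB (0.23, adjusted p = 0.121). Apoptosis genes had 3 of 7 higher and 2 lower in each comparison and DNA repair genes 3 of 8 higher and 2 lower in each, but CYCS and MSH6, each among the 3 higher against BJAB, lay below 0 and did not pass as deposited (−0.21 and −0.11) or after quantile normalization (−0.14 and −0.04). In all 2 of the 3 higher apoptosis calls and 3 of the 3 DNA repair calls against BJAB ended on each of these scales, and against L-428 2 (3 after quantile normalization) and 3. Their list medians against BJAB were −0.14 and −0.12, and −0.72 and −0.70 as deposited. There were, among secretory pathway genes, 4 of 11 higher and 3 lower against BJAB and 2 and 2 against L-428. As deposited and after quantile normalization HSP90B1, SSR1 and SRPRA, 3 of those 4 higher, did not pass against BJAB (0.25, 0.12 and −0.18 as deposited), nor did XBP1 and HSP90B1, the 2 higher against L-428 (0.15 and 0.21), and the list median against BJAB went from −0.06 to −0.64 as deposited. Markers of other blood cells were few. Of 9 myeloid genes 4 were higher and 1 lower against BJAB and 5 higher and 1 lower against L-428, none of those called by more than 1 log2 unit, and FCGR2A at −1.12 against L-428 did not pass. As deposited and after quantile normalization all 4 higher calls against BJAB ended, with CD14 at −0.08, CD68 at −0.06, CTSG at 0.002 and CTSS at −0.25 as deposited, and 4 of the 5 against L-428 ended, those of CD14, CD68, LYZ and CTSS. The T cell gene CD3D stood at 0.27 and 0.25 and did not pass, and GATA3 at 1.32 and −0.80 passed. The only measured B cell transcription factor of its list, SPIB, stood at 0.88 and 0.40, which passed, but at 0.295 and 0.06 as deposited, where the latter did not pass (adjusted p = 0.605). Of 5 reference genes 4 were higher against BJAB, and 2 were higher and 1 lower against L-428, with GAPDH at 0.80 and 0.77. As deposited their median against BJAB was −0.03, HPRT1 and YWHAZ turned to −0.03 and −0.21, and none of the 4 passed (GAPDH 0.22, adjusted p = 0.0874), against 2 of the 4 after quantile normalization, where 1 of 2 higher calls against L-428 ended too. Without L-428 array A or B, in fits with fewer degrees of freedom, PSME1 stood at −1.20 and −1.40 against L-428 (adjusted p = 0.0667 and 0.0571), GAPDH at 0.74 and 0.81 (0.0796 and 0.076) and GATA3 at −0.57 and −1.02 (0.205 and 0.101), no longer past the test. Nor were B2M at 0.71 (adjusted p = 0.0519) and GATA3 at 1.07 (0.0532) against BJAB without BJAB array B.

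**Figure D1:**
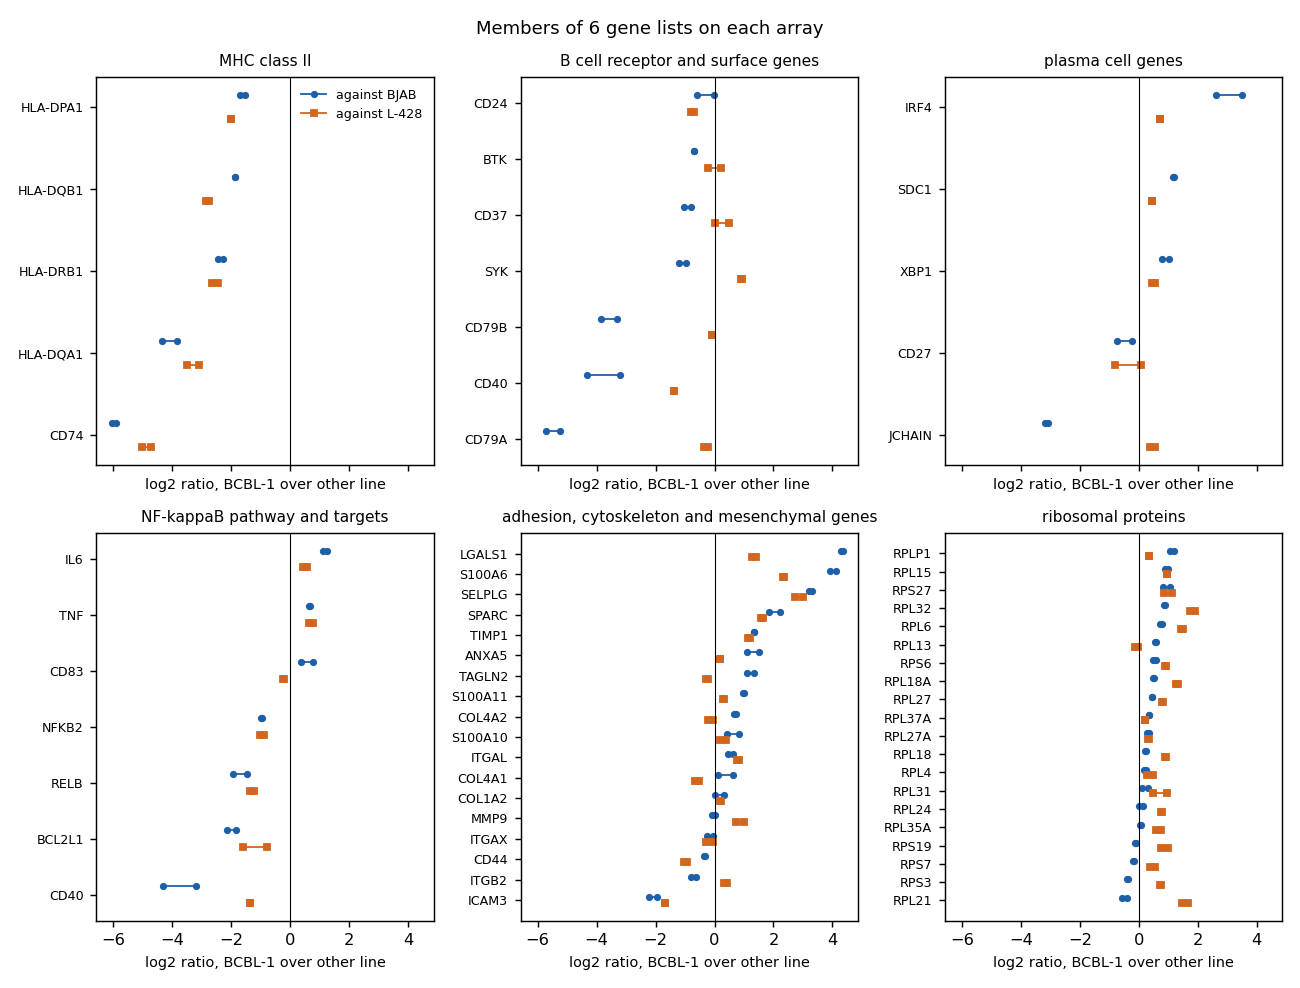
Log2 ratio of BCBL-1 over the other line, relative to the array median, for measured genes of 6 lists, with 1 gene not shown. Each point is 1 array and each line joins the 2 arrays of a pair, in blue against BJAB and in orange against L-428. All 5 MHC class II genes lie below 0 on all 4 arrays, whereas CD79A and CD79B lie far below 0 against BJAB alone.

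The third comparison set BJAB against L-428 through their common BCBL-1 channel, in which a dye effect that is equal on all arrays cancels. CD79A was higher in BJAB by 5.20 ± 0.21 (SE, 2 arrays per line, adjusted p = 0.00601), 36.8-fold, and CD79B by 3.50 ± 0.23. ARHGDIB was higher by 4.98 ± 0.13, B4GALT1 by 4.72 ± 0.65 and JCHAIN by 3.59 ± 0.13. LGALS1 was lower in BJAB at −2.99 ± 0.12, CYP19A1 at −2.94 ± 0.63, KCNJ8 at −2.77 ± 0.47, IRF4 at −2.32 ± 0.33 and YAP1 at −2.17 ± 0.12.

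Of 7 B cell receptor genes 5 were higher in BJAB and 0 lower, or 6 and 0 adjusted over the list alone, with a median of 2.0 (camera, adjusted p = 0.00583, or adjusted p = 0.675 with an estimated correlation). Ribosomal protein genes had 10 of 20 higher and 2 lower, with a median of 0.57 (adjusted p = 0.0102, or adjusted p = 0.675 with an estimated correlation). Adhesion genes had 2 of 19 higher and 8 lower, or 2 and 9 adjusted over the list alone, with a median of −0.43 that was −0.19 as deposited (adjusted p = 0.0308, or adjusted p = 0.675 with an estimated correlation). Of the 10 adhesion and 12 ribosomal calls 3 and 2 ended as deposited, and 0 of either after quantile normalization. The adhesion list's call ended without L-428 array A (adjusted p = 0.0591) and without array B (adjusted p = 0.0513). No other list passed, and in all 3 comparisons together the median and mean of a list had opposite signs in 10 of 54 list tests, 0 of them past camera. The median of a list changed sign as deposited in 14 of the 54, 0 of them past camera. Adjusted over the list alone, no count of any list moved by more than 2 genes. Of the MHC class II genes 1 was higher, CD74 at 1.11, which turned to −0.68 and did not pass after quantile normalization (adjusted p = 0.147), and 1 lower, HLA-DQB1 at −0.94.

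In all, 352 features passed limma's test, 151 higher and 201 lower in BJAB, against 258 and 92 in the values as deposited. At an adjusted p under 0.01 there were 7. Leaving out BJAB array A left 3, and leaving out BJAB array B, L-428 array A or L-428 array B left 0, against 634 at an unadjusted p under 0.05 with all arrays. Such a fit has 1 residual degree of freedom in place of 2, so these lost calls do not show that a gene rests on 1 array. Over those 4 fits ARHGDIB stood at 4.89 to 5.08, CD79A at 4.96 to 5.44 and YAP1 at −2.23 to −2.11, whereas B4GALT1 ran from 4.0 to 5.43 and CYP19A1 from −3.80 to −2.09. As deposited CYP19A1 did not pass (−2.71, adjusted p = 0.0514). Of 55 list members called in this comparison, 14 did not hold as deposited and 4 after quantile normalization.

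The last question was which genes set BCBL-1 apart from both lines. THBS1 (3.53 against BJAB and 3.08 against L-428), SELPLG (3.26 and 2.87), EDNRB (2.59 and 2.41), S100A6 (4.02 and 2.34) and OAS2 (2.27 and 2.19) were higher than in both. CD74 (−5.99 and −4.88), GSTP1 (−6.22 and −3.57), HLA-DQA1 (−4.11 and −3.30), OMG (−2.61 and −2.88) and TCF4, a transcription factor of B cells (−3.07 and −2.53), were lower than in both. Of 1586 features 257 were higher and 173 lower in both tests, where independent lists would share 120.1 and 76.4, and 49 passed both with opposite signs. BCBL-1 enters both ratios, so more sharing than between independent lists is built into the design. The excess alone does not show that BCBL-1 stands apart.

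**Figure D2:**
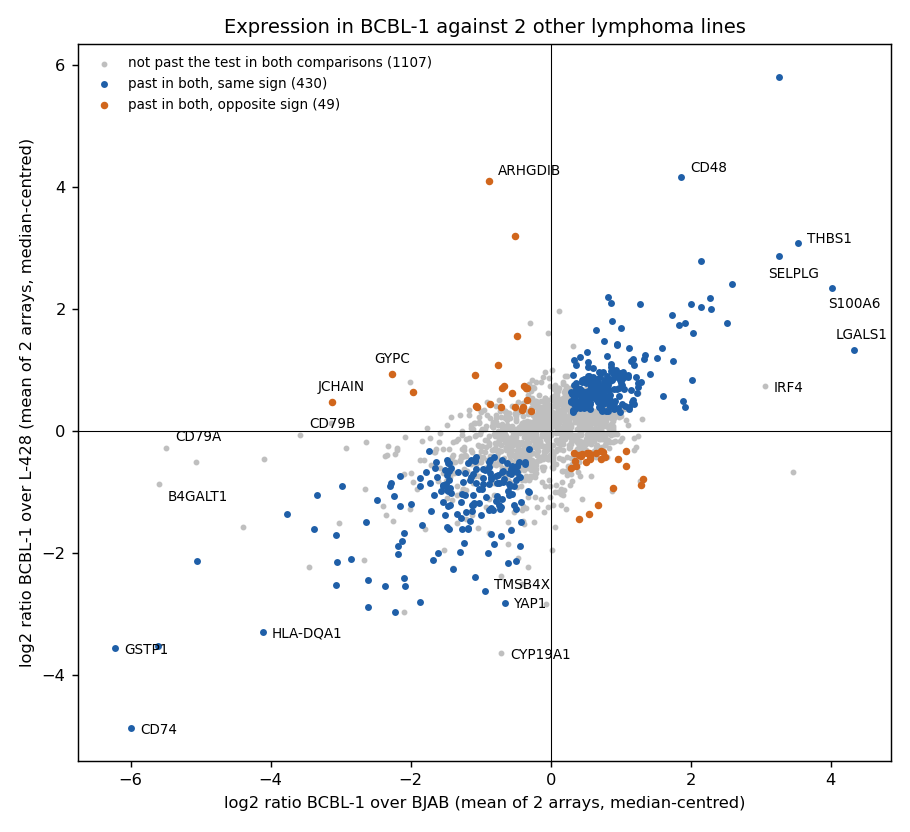
Mean log2 ratio of 2 arrays for each of 1586 features, BCBL-1 over BJAB on the horizontal axis and over L-428 on the vertical axis, relative to the array medians. Blue points passed the test in both with 1 sign (430) and orange points with opposite signs (49). CD74 and GSTP1 lie far below 0 on both axes and THBS1 and SELPLG far above, and the highest point has no gene symbol here.

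The ratios of both comparisons correlated across features at r = 0.626 (Spearman coefficient 0.605) with a covariance of 0.474. Unchanged features simulated with Cy5 noise shared by all arrays gave r = 0.672 and a covariance of 0.122, and with independent arrays r = 0.005. The shared noise was set as large as the spread between the arrays of a pair, and this choice fixes both of its simulated values. Its true size cannot be measured here. Part of the overlap may come from the shared channel, but how much is unknown. As deposited the split in both was 49 higher and 466 lower, and after quantile normalization 54 and 514. Without BJAB array A or B 273 and 260 features passed both tests, and without L-428 array A or B 50 and 47.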

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

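The test of the ribosomal protein genes in the values as deposited, that of their difference between BJAB and L-428, and the covariance test were chosen only after the result was seen, as were the repeats of the organ-restricted medians on all 53 genes and of the abundant-gene test on all 40. There were 49 features that passed both tests with opposite signs, and this selection all but fixes the outcome of the test of their difference. The 9 named genes among them at least 1.5-fold from 0 each way are given here as the difference BJAB over L-428. Opposite signs are relative to the array medians, which as deposited were −0.585 and −0.578 against BJAB and −0.349 and −0.337 against L-428. A positive value smaller than this offset lies below 0 as deposited, as do those of some of the 49. The positive values of these 9 genes exceed it, but are nearer to 0 as deposited. GYPC, a red cell glycophorin gene, differed by 3.20 (−2.26 against BJAB, 0.94 against L-428, with L-428 arrays at 1.28 and 0.60). SYK differed by 2.0 (−1.09 and 0.92) and ARHGDIB by 4.98 (−0.88 and 4.10). GATA3 differed by −2.12 (1.32 and −0.80) and the chaperone gene HSPA8 by −1.83 (0.88 and −0.95). PSMD8, of the proteasome, differed by 1.82 (−0.75 and 1.07), and PRKAR2A, a regulatory subunit of protein kinase A, by −1.88 (0.67 and −1.21). EHHADH, of peroxisomal fatty acid oxidation, differed by 1.40 (−0.70 and 0.70) and DMPK by 1.41 (−0.66 and 0.74). The L-428 arrays of EHHADH stood apart, at 0.385 and 1.007, the former less than 1.5-fold from 0.

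The sign of the deposited ratios was checked on B cell surface genes, which BJAB is known to carry and most of which effusion lymphoma lines are known to lack. The median of 7 B cell receptor and surface genes in the BJAB arrays was −1.087, with a standard error over genes of 0.755, and 6 of them were called lower and 0 higher. This goes with BCBL-1 over the other line, but the labels do not settle it. The same 7 genes gave the B cell result of the first comparison, so that result and this check are not separate evidence. Here and below, the SE given with a median is the SD over genes divided by the square root of their number. It is the error of a mean, and it takes genes as independent.

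The ratios against both lines moved together, and a dye or background effect at weakly expressed genes may be a part of this. In 53 genes restricted to other organs, chosen by family name, the medians were −0.004 (SE 0.101) against BJAB and −0.061 (SE 0.127) against L-428, but members were called both ways (17 higher and 7 lower, 9 higher and 10 lower), so these medians decide nothing. Their covariance was 0.194 (bootstrap SE 0.068), against 0.474 over all features. The medians were first taken over 49 genes, without those whose values had been seen earlier (0.01 and −0.055, with a covariance of 0.137), and had then been read as arguing against this explanation. Without channel intensities these genes are weak by name alone, so the explanation stays open, as does noise of the shared channel, and a difference between the lines was not tested apart from these.

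The median of the ribosomal protein genes stood above the array median against L-428. Centring moves all genes of an array alike, so it cannot change their distance from the array median, and the test of it decides nothing about that distance. It shows only that their median of 0.438 (SE over genes 0.105) lay above 0 as deposited too. The ribosomal protein genes lay 0.541 (SE 0.147) above 40 other abundant genes, although those also stood above 0 at 0.239, as did the 36 first used. Against BJAB the medians of both groups were close, at 0.329 and 0.294. Without channel intensities the 40 genes are abundant by name alone, and whether they are as bright as the ribosomal protein genes is unknown. A trend with brightness therefore stays open. A dye effect equal on all arrays cancels in BJAB over L-428, where the median of the ribosomal protein genes was 0.575 (SE 0.141). Camera estimated a correlation of 0.125 among these genes, so their SEs over genes are likely too small. Slide effects and signal from processed copies were not tested and stay open, and a difference between the lines may be proposed as a hypothesis alone.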

How the results depend on the processing

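All alternatives here were fixed in advance, and no test in this part was chosen only after the result was seen. Counts are given in the order BJAB, L-428, BJAB against L-428, both lines. An adjusted p under 0.01 gave 466, 183, 7 and 107, and limma's treat against a 1.5-fold change 161, 103, 30 and 49; both are stricter by construction. With the array letter as a replicate block, counts were 771, 453, 0 and 301, against 919, 670, 352 and 430 in the main fit. The block leaves 1 residual degree of freedom in place of 2, so these lower counts do not show an effect of the letter. Of the difference, 634 had an unadjusted p under 0.05 in the main fit. With the block 8 of 54 list tests were called, as without it. The letters share only a name (deviations correlated at −0.0359). Leaving out each array gave 495 to 785, 59 to 612, 0 to 3 and 47 to 273, with 1 array left in a pair. Under the remaining settings each count stayed within 1.5 times. The fold rule gave 583 at 1.5-fold, 82 at 3-fold, 415 as deposited and 315 to 334 on single arrays against BJAB, and 410, 63, and 241 to 242 on single arrays against L-428. Of 8 list calls, 0 held in camera with an estimated correlation, whose test has only 2 residual degrees of freedom and so could hardly pass any list. There 0 of 54 list tests had an unadjusted p under 0.05, the smallest being 0.0777. The adhesion list against BJAB had an estimated correlation of −0.055, below the preset 0.01. Its unadjusted camera p still went from 0.00206 to 0.0787, so these lost calls do not show that correlation among genes undoes a list. Of the same 54 list tests fry, which does not compare a list with other genes, called 33. Leaving out each array gave 7 to 8 list calls. Against BJAB, values as deposited turned CYCS to −0.214, CD68 to −0.064, HPRT1 to −0.027, YWHAZ to −0.208 and MSH6 to −0.108, and quantile normalization, which leaves the arrays uncentred, CYCS to −0.141, CD68 to −0.003, YWHAZ to −0.146 and MSH6 to −0.042. Their construction shows the cause, the offset of the array medians. Of 163 named gene values, 44 were no longer past the test at 0.01, 71 under treat, 25 as deposited (the 5 that turned included), and 59 and 62 without L-428 array A and B. Counting each probe on its own gave no other value, since no gene had more than 1 feature. Without intensities, signal over background is unknown.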

Other observations

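The families in this part, and so their tests, were chosen by name only after the result was seen. Of 15 genes of the respiratory chain and ATP synthase 9 rose and 2 fell against BJAB, with a median of 0.53 that was −0.06 as deposited, and 9 rose and 3 fell against L-428, with a median of 0.69 that was 0.34 as deposited. Members chosen after their values were seen were UQCRH, a subunit of complex III, at 1.84 and 1.74, and UQCRC2 of the same complex at −1.02 and −1.18. The family did not pass camera (adjusted p = 0.156 and 0.261).

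Of 8 G protein alpha subunits 5 were higher in BJAB than in L-428 and 0 lower, with a median difference of 0.88 (1.12 as deposited), among them GNAS at 2.08, GNAL at 1.94 and GNAZ at 1.18 (camera, adjusted p = 0.126). Against BJAB 0 of them were higher and 3 lower, and against L-428 3 higher and 0 lower, with medians of −0.14 and 0.33 that were −0.72 and −0.02 as deposited. Of 8 proteasome and chaperonin genes 6 rose and 0 fell against L-428, with a median of 0.65 that was 0.31 as deposited (adjusted p = 0.126). Against BJAB 4 rose and 2 fell, CCT5 to −1.0 and PSMD8 to −0.75, with a median of 0.34 that was −0.25 as deposited (adjusted p = 0.575). Of 13 cathepsin and lysosomal enzyme genes 6 rose and 3 fell against BJAB, and 6 and 1 against L-428, with medians of 0.33 and 0.43 that were −0.25 and 0.08 as deposited. The lysosomal lipase gene LIPA stood at −2.08 and −2.55, far from HEXA at 1.05 and 0.36, and these genes were chosen after their values were seen. HEXA did not pass limma's test against L-428 (adjusted p = 0.077).

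Lower ratios were noisier. The median absolute difference between the arrays of a pair was 0.468 for mean ratios below −1 and 0.13 for those above 1 against BJAB, and 0.339 and 0.137 against L-428. Values were missing on both BJAB arrays for 6 features, CXCL10, GC, GNRH1, MAOB, PTPRN2 and RFX5. Among the 27 features left out of the fit for a missing value, the highest BJAB value present was −1.331, of PRKCQ. The fit thus lost features with low ratios against BJAB. List members lost this way were RFX5, CXCL10 and BIRC3, the last at −2.63 on BJAB array A and −3.02 and −2.33 against L-428.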
